A study of Solanum tuberosum with 8 samples.

How the data were processed

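Leaf poly(A) RNA of potato (Solanum tuberosum) was sequenced in 8 libraries, 1 for each of 8 groups. The groups crossed 4 plant backgrounds with feeding by Colorado potato beetle (CPB) larvae or none. Of the backgrounds, H was the healthy cultivar Igor, PVY was Igor grown with a secondary infection by the NTN strain of potato virus Y, NT was the non-transformed cultivar Desiree, and coi1 was Desiree in which the jasmonate receptor gene COI1 was silenced by RNA interference. Libraries from infested plants are called CPB_H, CPB_PVY, CPB_NT and CPB_coi1 below, and those from non-infested plants CONT_H, CONT_PVY, CONT_NT and CONT_coi1. Per the labels' protocols, young larvae fed on upper leaves of 4 plants in each glass container, control plants stood outside the containers in the same chamber, and leaves were taken after 24 hours. Container and infestation are therefore confounded in every comparison of infested with non-infested plants. Per the labels' protocols, RNA was extracted from about 150 mg of leaf with a column kit, pooled over plants, treated with DNase I and enriched on oligo(dT) beads, and Illumina libraries were made at a sequencing company. How many plants entered a pool, the aligner, the counting tool and the annotation version are not given in the sources used here.

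The authors deposited RPKM values, reads scaled by transcript length and library depth, for 35609 representative genes in the 8 libraries, per the file headers. The table also gives a length and an annotation for each row. Identifiers were of the Sotub type in 20809 rows and of the PGSC type in 9509 rows, and 5291 rows, mostly expressed sequence tags, had another type. Gene descriptions were taken from the deposited annotation, because 0 of the identifiers matched the RefSeq gene table of the potato assembly SolTub_3.0. A genome was not used here, so no positions are given. Of the lengths, 90.0% were multiples of 3, so they are mostly coding lengths. Multiplied by length and by a total fitted to each library, the values became whole counting units within 0.03 units beyond their rounding in 100.0% of the values judged, which were those under 60 units. Rows without a unit stood at the value of 0.5 units. Whether a unit is a read or a read pair is not given in the sources used here.

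The fitted totals, to the nearest 10000, were 17970000 units for CPB_PVY, 16680000 for CONT_PVY, 17820000 for CPB_H, 18620000 for CONT_H, 17320000 for CPB_coi1, 17500000 for CONT_coi1, 17640000 for CPB_NT and 18080000 for CONT_NT. Some folds of named genes are given with 95% counting intervals from the unit counts (exact, Clopper-Pearson), and a share of 0 allows up to 3 units. Intervals and limits cover counting error only.

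Genes were kept when they had an RPKM of at least 1 in at least 2 libraries, which left 18842 genes, 14939 of them described. Values were analysed as log2(RPKM + 1). A linear model with background as a block and infestation as a factor was fitted to the 8 libraries with limma 3.58.1 in R 4.3.3 (eBayes with trend, 3 residual degrees of freedom, prior degrees of freedom 4.28). Its contrasts were infested minus non-infested over all backgrounds, PVY minus H, and coi1 minus NT. Tests were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The spread in this model is the disagreement between the 4 infested and non-infested pairs, so a response that truly differs between backgrounds counts as error. The same spread serves the contrasts between backgrounds, where the infested and the non-infested library of a background stand in for replicates. No group was repeated, so spread between pools of the same group was not measured on its own. A contrast of cultivars (H minus NT) was added after the data were seen. Comparisons of a single pair of libraries have no replicate and were given no test. For these, genes at least 2-fold higher or lower were counted, and the median log2 ratio of each gene list was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Differences of responses (PVY minus H, coi1 minus NT) were treated the same way, and correlations of responses run across genes, which are not independent replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

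A total of 27 gene lists were fixed from words in the descriptions, before the data were examined, together with the comparisons, tests and most alternatives. They covered jasmonate biosynthesis, jasmonate signalling, proteinase inhibitors, anti-digestive enzymes, pathogenesis-related proteins, the salicylic acid pathway, the ethylene pathway, volatile terpene and green leaf aldehyde enzymes, phenylpropanoid and flavonoid enzymes, sterol and isoprenoid precursor enzymes, WRKY transcription factors, disease resistance receptors, antiviral RNA silencing, light harvesting and photosystem, Rubisco and Calvin cycle, starch and sucrose metabolism, heat shock proteins and chaperones, water deficit and abscisic acid, cell wall loosening and remodelling, auxin response, glutathione transferases and peroxidases, cytochrome P450 enzymes, the circadian clock, cell division and histones, cytosolic ribosomal proteins, tuber storage proteins, and pollen and flower proteins. A gene can be in several lists. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Members were also counted by adjusted p over the list alone.

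Named genes followed a fixed rule. In the infestation contrast these were the 12 highest and 12 lowest described genes that passed the threshold with the same sign in all 4 pairs, and in the virus and coi1 contrasts the 8 highest and 8 lowest over their pairs. In each single comparison they were the 6 highest and 6 lowest described genes with an RPKM of at least 5 in a library compared. Each list added up to 4 members with the largest ratio. Any other gene that the text names was chosen after its values were seen.

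The steps were tested on simulated data with known changes. The simulation of the infestation contrast used 18842 genes and the spread of the real fit. Changed genes had a mean RPKM of at least 5 and the same fold in all 4 backgrounds. The model recovered 46% of genes changed 2-fold, 96% at 4-fold, 100% at 8-fold and 98% at 16-fold, with 5 false calls among 175. Recovery of genes with lower values, or of folds that differ between backgrounds, was not measured. Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter or a filter at 5 RPKM, scaling by median of ratios or quantile normalization, eBayes without trend, leaving out each pair, no background block, and models of the 4 Igor or 4 Desiree libraries alone. Added after the data were seen were limma voom on the recovered units and a run without the virus rows with RPKM rescaled. Rows of virus sequence stayed in the table in the other runs.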

Results

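The data were gene expression values of potato leaves, given as RPKM for 35609 representative genes in 8 libraries, 1 pooled library per group. Each of 4 backgrounds contributed a library from plants fed on by Colorado potato beetle larvae for 24 hours and a library from non-infested plants. The backgrounds were healthy Igor (H), Igor with potato virus Y (PVY), non-transformed Desiree (NT) and COI1-silenced Desiree (coi1). Depth ran from 16680000 to 18620000 counting units per library, between 17497 and 17837 genes reached an RPKM of 1, and the 10 most abundant genes took 6.1% to 12.3% of the units. No group had a replicate, so differences between a single pair of libraries have no replicate check and carry no p-value.

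Virus sequence matched the labels of the PVY libraries. The table held 8 rows described as potato virus Y polyprotein, the precursor of all proteins of this virus. Together they took 3.82% of the units of CONT_PVY (95% interval 3.81 to 3.83) and 2.18% of CPB_PVY (2.18 to 2.19). The row TC218757 reached an RPKM of 49850 in CONT_PVY and 29261 in CPB_PVY. The virus rows had 629 units in CONT_H, 472 in CPB_H and 352 in CONT_NT, 1 unit in each of CONT_coi1 and CPB_coi1, and 0 in CPB_NT, which allows a share of up to 1.7e-05%. COI1, the silenced gene, could not be checked in this way. The only row described as COI1, CV506608, a partial sequence tag, had 0 units in all 8 libraries, which allows an RPKM of up to 0.321 in CONT_H and up to 0.358 in CONT_PVY. Neither the silencing in the coi1 libraries nor its absence elsewhere can be read from it, and rows without a description were not searched for COI1.

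**Figure D1:**
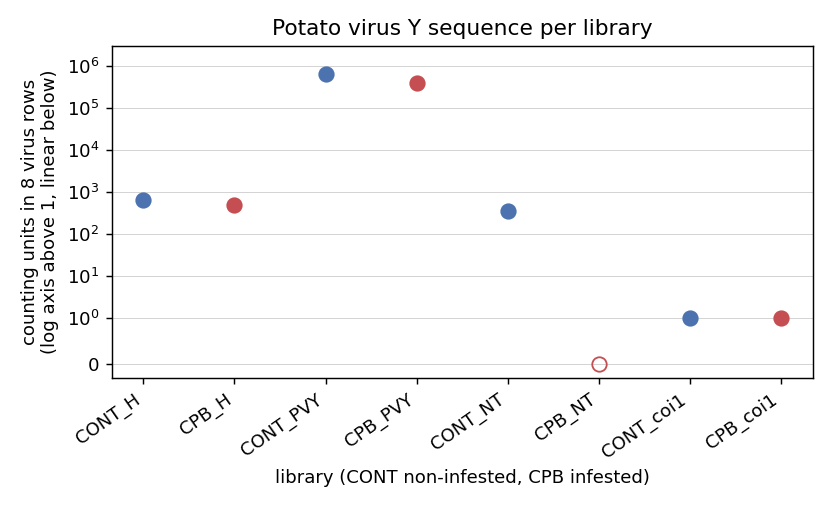
Counting units of the 8 potato virus Y rows (vertical axis, log scale above 1 unit) in each of the 8 libraries (horizontal axis), blue for non-infested and red for infested plants, with an open circle for 0. The points of CONT_PVY (637355 units) and CPB_PVY (392352 units) lie far above the others, and CONT_H, CPB_H and CONT_NT hold 629, 472 and 352 units.

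Beetle feeding was compared with no feeding over all 4 backgrounds, to ask which leaf transcripts respond in common. The genes that rose included peroxidase, pathogenesis-related and jasmonate ZIM-domain genes, and those that fell included 2 of starch synthesis. Peroxidase 4 (Sotub04g026540.1.1), of the family of peroxide-using enzymes that act on the cell wall, rose from an RPKM of 4.62 to 91.4 in H, 8.59 to 176 in PVY, 2.69 to 54.7 in NT and 0.38 to 23.4 in coi1 (log2 change 4.08 ± 0.16 SE, adjusted p = 0.000494, 4 of 4 pairs, limma with Benjamini-Hochberg adjustment). The jasmonate ZIM-domain repressor gene JAZ1 (Sotub12g008780.1.1), itself switched on by jasmonate, rose from 9.69 to 202 in H, 13.7 to 165 in PVY, 7.74 to 114 in NT and 2.47 to 30.9 in coi1 (log2 change 3.67, adjusted p = 0.00319). Of 18842 genes tested, 162 rose and 39 fell.

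Among the genes that rose in all 4 pairs, the largest log2 changes were those of Cationic peroxidase 1 (PGSC0003DMG400011948, 5.66 ± 0.92 SE, adjusted p = 0.0455), Peroxidase Sotub01g042120.1.1 (4.94, adjusted p = 0.0125) and the antifungal Osmotin-like protein Sotub08g026710.1.1 (4.90, adjusted p = 0.0421). Plastid-targeted protein 2 (PGSC0003DMG400030843, 4.23), Endoglucanase Sotub04g024180.1.1 (4.16), Prephenate dehydrogenase family protein Sotub09g012050.1.1 (4.10), Fatty acid desaturase PGSC0003DMG400035878 (4.08) and Subtilisin-like protease Sotub10g024680.1.1 (3.97) followed, with adjusted p between 0.0122 and 0.0265. Thaumatin-like protein Sotub06g027980.1.1 (3.85), Lipoxygenase homology domain-containing protein 1 (Sotub03g021410.1.1, 3.82) and Beta-glucanase Sotub01g017930.1.1 (3.81) also rose, with adjusted p of 0.0125, 0.027 and 0.0298. An enzyme of ethylene synthesis, 1-aminocyclopropane-1-carboxylate oxidase 1 (Sotub08g008060.1.1), rose by 3.76 (adjusted p = 0.0173).

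The genes that fell in all 4 pairs included enzymes of starch and pigment synthesis. Glucose-1-phosphate adenylyltransferase (Sotub01g047210.1.1), which makes the sugar donor for starch, went from 347 to 67.1 in H, 90.7 to 39.0 in PVY, 619.5 to 70.9 in NT and 533 to 94.8 in coi1 (log2 change -2.28, adjusted p = 0.027). Granule-bound starch synthase (Sotub08g026990.1.1), which makes amylose, changed by -2.11 (adjusted p = 0.0255). Of the flavonoid enzymes on the route to anthocyanins, Anthocyanidin synthase (Sotub11g014460.1.1) changed by -1.70 and Dihydroflavonol-4-reductase (Sotub02g033180.1.1) by -1.69, with adjusted p of 0.0314 and 0.0429. Other genes that fell were those of TPR domain proteins (Sotub06g023660.1.1, -3.38, adjusted p = 0.0469, and Sotub08g021560.1.1, -2.43, adjusted p = 0.0231), Amino acid selective channel protein (Sotub06g010030.1.1, -2.14), Ferric reductase oxidase (Sotub01g039500.1.1, -1.96), which acts in iron uptake, and Gibberellin 20-oxidase-1 (Sotub03g007160.1.1, -1.91), which acts in gibberellin synthesis. Their adjusted p were 0.0156, 0.0128 and 0.0491. UDP-glucosyltransferase family 1 protein (Sotub10g029070.1.1, -1.90, adjusted p = 0.0128), Tyrosine-specific transport protein (Sotub04g014220.1.1, -1.86, adjusted p = 0.0308) and Carboxyl methyltransferase (Sotub02g029720.1.1, -1.71, adjusted p = 0.0128) completed the set of 12.

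Of the defence lists, proteinase inhibitors, which block insect gut proteases, had a median log2 change of 1.03 over 66 members and 57 positive values (camera adjusted p = 5.23e-13, and adjusted p = 0.217 with an estimated correlation). In this list 26 members rose adjusted over the list alone and 2 over all genes, Proteinase inhibitor I Sotub10g028670.1.1 (2.52) and Metallocarboxypeptidase inhibitor Sotub07g007650.1.1 (1.48). Jasmonate biosynthesis had a median of 0.91 over 22 members (adjusted p = 1.7e-08, and 0.19 as adjusted p with an estimated correlation), with 12 higher and 1 lower adjusted over the list alone and 4 higher over all genes. These 4 were Allene oxide synthase (Sotub04g032980.1.1, 2.52), which makes the jasmonate precursor, and 3 genes that carry only a lipoxygenase homology domain, namely Sotub03g021410.1.1 and the Wound/stress proteins Sotub03g021520.1.1 and Sotub03g021420.1.1. Jasmonate signalling had a median of 1.09 over 15 members (adjusted p = 2.51e-05, and 0.232 as adjusted p with an estimated correlation), with 8 higher adjusted over the list alone and 2 over all genes, JAZ1 and Jasmonate ZIM domain 1 (Sotub03g034750.1.1, 2.09). Anti-digestive enzymes, which lower the food value of leaf protein, had a median of 2.06 over 9 members (adjusted p = 0.00126, and 0.217 as adjusted p with an estimated correlation), with 6 higher adjusted over the list alone. Over all genes limma called 0 of them, with 6 at an unadjusted p under 0.05, and limma voom called 3.

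Pathogenesis-related proteins had a median of 0.74 over 55 members (adjusted p = 1.7e-08, and 0.217 as adjusted p with an estimated correlation), with 18 higher adjusted over the list alone and 8 over all genes, such as Pathogenesis-related protein 1 (Sotub01g043930.1.1, 2.05). Volatile terpene and green leaf aldehyde enzymes, which make scents released by damaged leaves, had a median of 1.26 over 29 members (adjusted p = 8.67e-08, and 0.217 as adjusted p with an estimated correlation). In this list 15 were higher adjusted over the list alone and 1 over all genes, Alpha-humulene/(-)-(E)-beta-caryophyllene synthase (Sotub01g039000.1.1, 3.07, adjusted p = 0.0416). Glutathione transferases and peroxidases had a median of 0.19 over 118 members (adjusted p = 1.33e-06, and 0.232 as adjusted p with an estimated correlation), with 28 higher and 4 lower adjusted over the list alone and 14 higher and 1 lower over all genes. The 14 were peroxidases apart from Alpha-dioxygenase Sotub02g035780.1.1, an enzyme of fatty acid oxidation, and the gene that fell was Superoxide dismutase Sotub06g015020.1.1 (-1.60). WRKY transcription factors, regulators of defence genes, had a median of 0.26 over 54 members (adjusted p = 0.00279, and 0.622 as adjusted p with an estimated correlation), with 11 higher and 3 lower adjusted over the list alone, and 2 higher and 1 lower over all genes. Cytosolic ribosomal proteins had a median of 0.26 over 264 members (adjusted p = 4.35e-06, and 0.622 as adjusted p with an estimated correlation). Limma called 0 of them, with 39 at an unadjusted p under 0.05, and voom called 0. The medians of these last 2 lists were not above 0 in every pair, with -0.24 for WRKY in PVY and -0.054 for ribosomal proteins in NT. Nor were those of proteinase inhibitors (-0.15, percentile 8.78) and anti-digestive enzymes (-0.13, percentile 29.1), which lay under 0 in coi1. Water deficit and abscisic acid genes had a median of 0.13 over 66 members (adjusted p = 0.0266, and 0.217 as adjusted p with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. Over all genes limma called 0, with 13 at an unadjusted p under 0.05, and voom called 3. Without the PVY pair or the NT pair the adjusted p of that list was 0.071 and 0.0653.

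Lists with lower values in infested plants over the 4 backgrounds were those of photosynthesis, starch, antiviral RNA silencing and receptors. Not every pair went that way, since photosystem genes had a median of 0.45 in PVY and receptors 0.05 in NT, both at percentile 100. Light harvesting and photosystem genes had a median of -0.58 over 91 members, 23 of them positive (adjusted p = 0.00265, and 0.622 as adjusted p with an estimated correlation). Over all genes 2 members passed the threshold, both of them Blue copper proteins (Sotub07g008350.1.1, 3.28, and Sotub03g030140.1.1, 2.83), which rose and are not photosystem parts, and adjusted over the list alone 4 were higher and 1 lower. Without the H pair the adjusted p of this list was 0.434, and without the coi1 pair 0.115. Rubisco and Calvin cycle genes had a median of -0.57 over 18 members (adjusted p = 0.00237, and 0.237 as adjusted p with an estimated correlation), and limma called 0 of them also adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 0 by voom. Starch and sucrose metabolism had a median of -0.24 over 46 members (adjusted p = 0.014, and 0.217 as adjusted p with an estimated correlation), with 8 lower and 2 higher adjusted over the list alone and 2 lower over all genes, the starch enzymes named above. Without the H pair its adjusted p was 0.071. Antiviral RNA silencing had a median of -0.22 over 21 members (adjusted p = 0.00265, and 0.288 as adjusted p with an estimated correlation), with 0 called by limma, 4 at an unadjusted p under 0.05 and 0 by voom. Disease resistance receptors had a median of -0.11 over 266 members (adjusted p = 0.0448, and 0.656 as adjusted p with an estimated correlation). Limma called 0 of them, with 16 at an unadjusted p under 0.05, and voom 1, and the list's adjusted p was 0.271 without the H pair, 0.35 without the PVY pair and 0.069 without the coi1 pair. None of the list calls in the 3 contrasts described here held with an estimated correlation.

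The other 12 lists did not pass in this contrast. The ethylene pathway had a median of 0.025 over 153 members (adjusted p = 0.0688), which was -0.014 with quantile normalization, with 5 higher and 2 lower over all genes and 12 and 6 adjusted over the list alone. Phenylpropanoid and flavonoid enzymes had a median of 0.12 over 91 members (adjusted p = 0.0779), with 1 higher and 2 lower over all genes and 22 and 14 adjusted over the list alone. This list passed without the H pair (adjusted p = 0.0421), the NT pair (0.0181) or the coi1 pair (0.0389), and the ethylene pathway passed without the coi1 pair (0.0207). Sterol and isoprenoid precursor enzymes had a median of -0.15 (43 members, adjusted p = 0.131, and 0.0481 without the coi1 pair). Cell division and histones had a median of -0.10 (256 members, adjusted p = 0.139), with 3 higher over all genes and 3 adjusted over the list alone, of which Cyclin B2 (Sotub04g007690.1.1, 2.16) is a cell cycle gene and the F-box proteins Sotub01g009740.1.1 and Sotub01g037800.1.1 belong to protein degradation. Cell wall loosening and remodelling had a median of 0.011 (123 members, adjusted p = 0.193), with 3 higher over all genes and 9 higher and 1 lower adjusted over the list alone, and it passed without the H pair (0.0105). The circadian clock had a median of -0.13 (48 members, adjusted p = 0.155), with 1 higher and 1 lower adjusted over the list alone. Auxin response had a median of -0.13 (118 members, adjusted p = 0.246), with 2 higher over all genes. Cytochrome P450 enzymes had a median of -0.014 (198 members, adjusted p = 0.262), which was 0.010 with median of ratios scaling. The mean of the P450 list was 0.12 and its test pointed up, with 7 higher and 2 lower over all genes, and without the coi1 pair its adjusted p was 0.0481. Tuber storage proteins had a median of 0.095 (20 members, adjusted p = 0.369, 1 higher over all genes), the salicylic acid pathway -0.14 (8 members, adjusted p = 0.448), and pollen and flower proteins -0.11 (29 members, adjusted p = 0.867). For heat shock proteins and chaperones the median was -0.06 and the mean 0.013 (213 members, adjusted p = 0.971), with 2 higher over all genes.

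The count of 201 genes depended on which pairs and which scaling were used. Without the H pair 2 genes passed (Peroxidase 4 and JAZ1), without the NT pair 21, without the PVY pair 304 and without the coi1 pair 465, and median of ratios scaling gave 82.

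Within each background, more proteinase inhibitors had higher values after feeding in H, PVY and NT than in coi1 (39, 34 and 29 of 66 members at least 2-fold higher, against 10). Cysteine proteinase inhibitor (Sotub06g027390.1.1) stood at an RPKM of 7.16 in CONT_H and 5180.3 in CPB_H, a ratio of 723.5 (95% counting interval 620.1 to 849.2). It went from 4.29 to 2109 in the PVY pair, a ratio of 492 (398 to 614), and from 173 to 22874 in the NT pair, a ratio of 132 (128 to 137). In the coi1 pair it was 26.3 without and 4.13 with feeding. Over the 4 pairs its log2 change was 5.65 with an adjusted p of 0.175, so it did not pass. Aspartic protease inhibitor 1 (Sotub03g015970.1.1) was at 3109.5, 1000.7 and 14132 in CPB_H, CPB_PVY and CPB_NT, and at 1.27 in CPB_coi1. Proteinase inhibitor II (Sotub03g012360.1.1) reached 5169, 4656 and 6985 in the same infested libraries, ratios of 68.0, 25.4 and 221 to their controls. In coi1 it had 3 units in CPB_coi1, a ratio of 0.0572 (0.0114 to 0.176). Polyphenol oxidase (Sotub08g017890.1.1), which browns and cross-links leaf protein, went from 2.62 to 1099.8 in H, 0.66 to 114 in PVY and 1.67 to 629.9 in NT, and from 1.03 to 0.28 in coi1. Threonine dehydratase (Sotub09g008430.1.1), which breaks down an amino acid that larvae need, was at 1652, 758 and 4411 in CPB_H, CPB_PVY and CPB_NT and at 0.61 in CPB_coi1. Other genes of these lists had higher values with feeding in the coi1 pair, such as Kunitz-type trypsin inhibitor Sotub03g015850.1.1 (1.24 to 212) and Proteinase inhibitor type-2 (Sotub07g020290.1.1, 35.9 to 785).

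**Figure D2:**
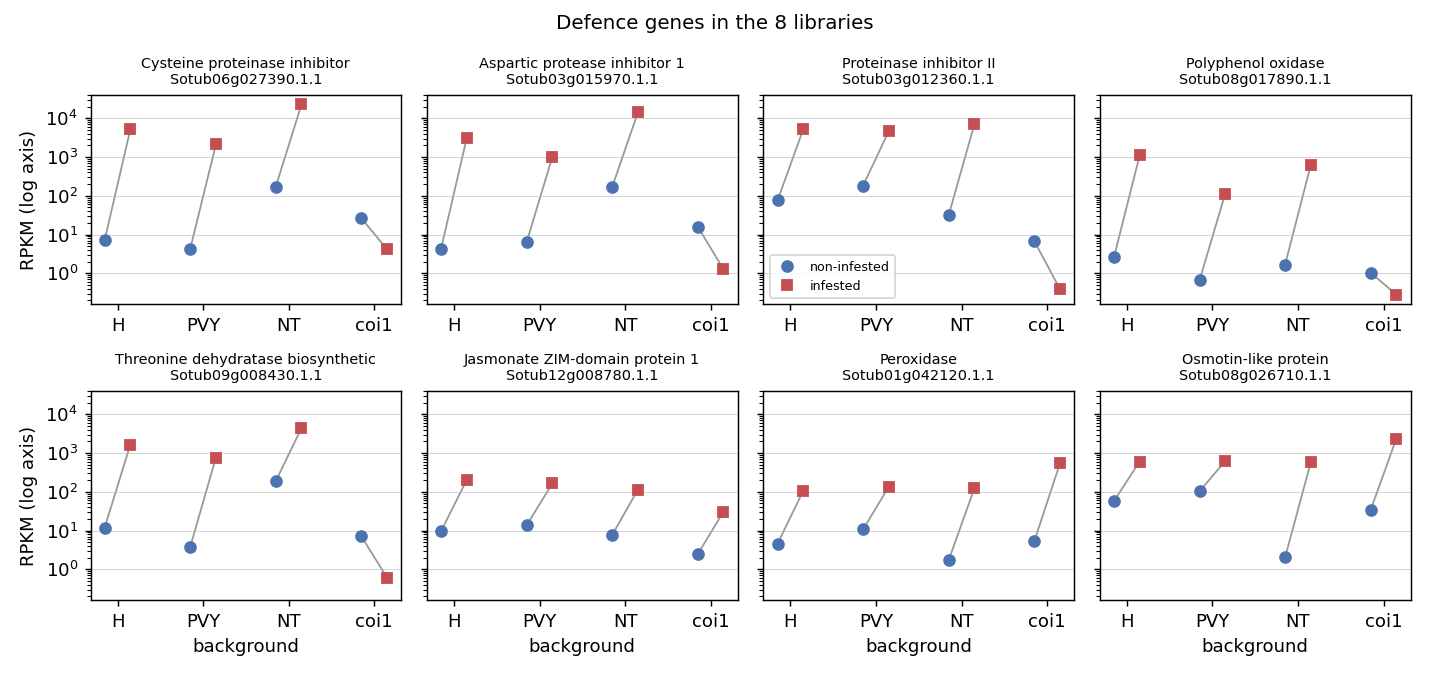
RPKM (vertical axis, log scale) of 8 defence genes in the 4 backgrounds (horizontal axis), with a circle for the non-infested and a square for the infested library of each background. In the first 5 panels the infested library is the higher of the pair in H, PVY and NT and the lower in coi1 (Cysteine proteinase inhibitor, 26.3 to 4.13), while JAZ1, Peroxidase Sotub01g042120.1.1 and Osmotin-like protein are higher in the infested library of all 4 backgrounds.

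The medians of 5 lists of jasmonate, anti-feeding and volatile genes were lower in coi1 than in the other backgrounds. Proteinase inhibitors had a median log2 ratio of 1.28 in H, 1.18 in PVY and 0.85 in NT, each above all 10000 matched random lists, and -0.15 in coi1 (percentile 8.78). Of its 66 members, 0, 1, 2 and 17 were at least 2-fold lower. Jasmonate signalling had medians of 1.98, 1.39 and 1.21, and 0.07 in coi1 (percentile 66.3). Anti-digestive enzymes had medians of 2.35, 1.35 and 2.44, and -0.13 in coi1 (percentile 29.1). Taken by gene, the coi1 minus NT response of the anti-digestive enzymes had a median of only -0.253 (percentile 7.06). Of their 9 members, 3 were at least 2-fold lower and 2 higher, so the drop was not shared by the whole list. Volatile terpene and green leaf aldehyde enzymes had medians of 1.06, 0.52 and 1.47, and 0.01 in coi1 (percentile 57.4). Jasmonate biosynthesis had medians of 1.31, 0.92 and 0.71, and 0.28 in coi1 (percentile 96.4), but means of 1.19, 1.06, 1.15 and 1.11. Pathogenesis-related proteins differed from these in having like medians in all backgrounds, 0.55 in H, 0.49 in PVY, 0.37 in NT and 0.51 in coi1, each at percentile 100. Their means were 0.665, 0.723, 0.955 and 1.41. Gene by gene, the coi1 minus NT response of this list had a median of 0.315 (percentile 98.35). At least 2-fold, 18 members were higher and 3 lower. In the coi1 pair, Endochitinase 4 (PGSC0003DMG400026855), which breaks down fungal walls, went from 2.8 to 514, Ripening-related protein 3 (Sotub11g026240.1.1) from 1.09 to 349 and another Polyphenol oxidase (Sotub08g019390.1.1) from 0.38 to 194.

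Among 18842 genes, 1339 were at least 2-fold higher and 666 lower in the H pair, 942 and 534 in the PVY pair, 1116 and 944 in the NT pair, and 1717 and 1575 in the coi1 pair. Scaled by median of ratios, the counts were 1098 and 928 in H, 1152 and 351 in PVY, 1296 and 739 in NT, and 1659 and 1580 in coi1. The median of all genes was 0.13 in H, -0.15 in PVY, -0.095 in NT and -0.009 in coi1. H and PVY shared 455 of their higher genes, against 66.9 for independent lists of those sizes, and NT and coi1 shared 529, against 101.7. Of the lower genes, H and PVY shared 41, against 18.9, while 65 of the 666 genes lower in H were at least 2-fold higher in PVY, and NT and coi1 shared 307, against 78.9.

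**Figure D3:**
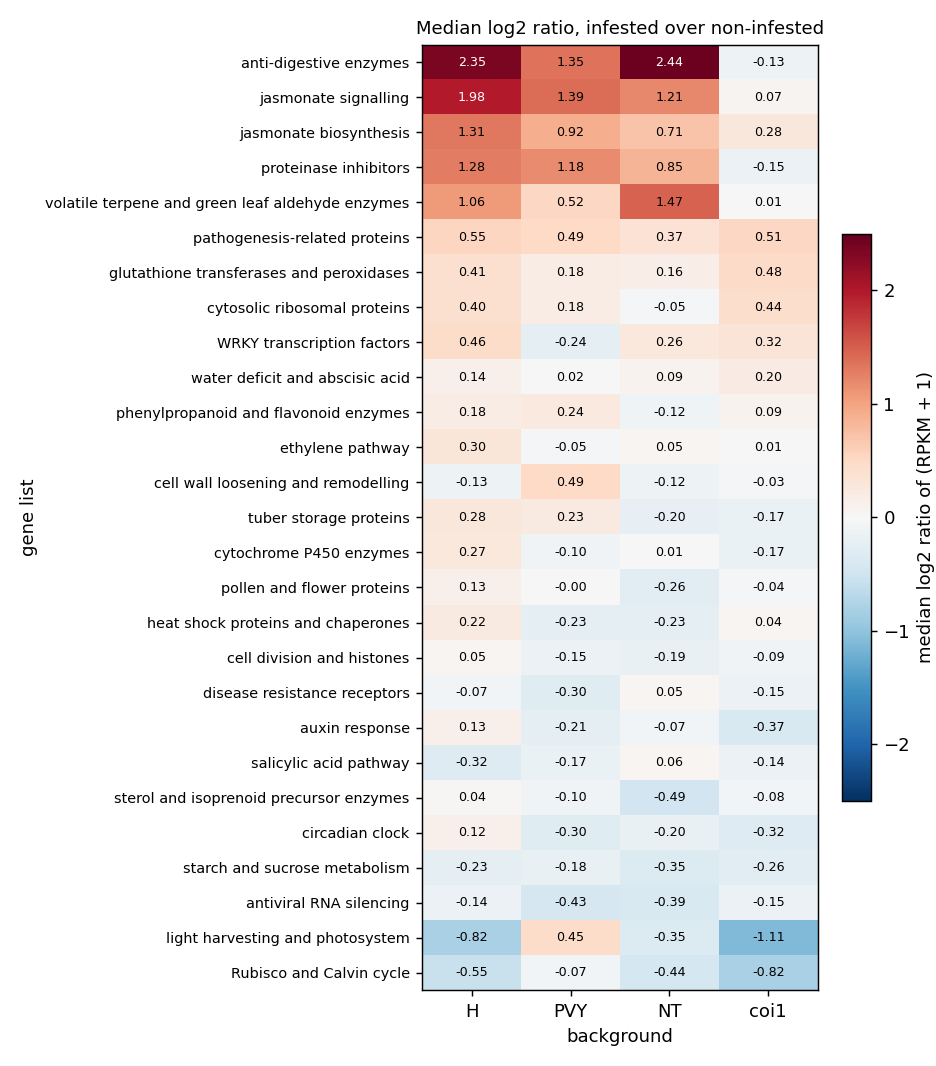
Median log2 ratio of infested over non-infested plants (colour and printed value) for the 27 gene lists (vertical axis) in the 4 backgrounds (horizontal axis). Proteinase inhibitors stand at 1.28, 1.18 and 0.85 in H, PVY and NT and at -0.15 in coi1, and light harvesting and photosystem genes stand at 0.45 in PVY and below 0 in the other backgrounds.

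The response of PVY plants was set against that of H plants, the comparison behind the question in the series title of whether the virus hinders defence against the beetle. Photosynthesis genes were the clearest difference. Chlorophyll a-b binding protein 37 (Sotub12g011480.1.1), a light-harvesting protein, went from an RPKM of 3760 to 537 in the H pair and from 1158 to 2200.4 in the PVY pair. Light harvesting and photosystem genes had a median log2 ratio of -0.82 in H and 0.45 in PVY. The difference had a median of 1.13 (percentile 100), with 52 of 91 members at least 2-fold higher and 7 lower. Photosystem II polypeptide (Sotub12g013820.1.1) went the other way, from 19.8 to 47.3 in H and from 201 to 22.8 in PVY. Rubisco and Calvin cycle genes had a median of -0.55 in H and -0.07 in PVY, the latter 0.084 with median of ratios scaling, and a difference of 0.74 (percentile 100). Cell wall loosening and remodelling genes had medians of -0.13 and 0.49 and a difference of 0.50 (percentile 100). WRKY transcription factors had medians of 0.46 and -0.24 and a difference of -0.74 (percentile 0), with 17 of 54 members at least 2-fold lower and 0 higher. Heat shock proteins and chaperones differed by -0.41 (percentile 1.39) and the ethylene pathway by -0.42 (percentile 0.54).

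Many anti-feeding genes had higher values after feeding in both backgrounds, with lower levels in infested PVY plants for some. Proteinase inhibitors differed in their response by a median of -0.47 (percentile 1.15), with 16 of 66 members at least 2-fold lower in PVY and 6 higher, against a median of -0.30 for all genes. This percentile was 6.65 with a pseudocount of 0.1, 3.43 with a filter at 5 RPKM and 5.40 among lists matched also on length. Kunitz-type protease inhibitor Sotub03g016070.1.1 was at 47.4 in CPB_H and 1.05 in CPB_PVY, Polyphenol oxidase Sotub08g017890.1.1 at 1099.8 and 114, and Proteinase inhibitor I Sotub09g026630.1.1 at 678 and 101. Proteinase inhibitor II was at 5169 and 4656. Kunitz-type tuber invertase inhibitor (PGSC0003DMG400010146), which is in none of the lists and acts on a sucrose-splitting enzyme of the plant, was at 352 and 17.7. Jasmonate biosynthesis (-0.22, percentile 65.5), jasmonate signalling (-0.31, percentile 43.2), anti-digestive enzymes (0.00, percentile 88.6) and volatile terpene and green leaf aldehyde enzymes (-0.37, percentile 19.8) lay within the central 95% of matched lists. Pathogenesis-related proteins did too (-0.19, percentile 85.6), with a median of 0.005 after quantile normalization. Across genes, which are not independent replicates, the H and PVY responses had a Pearson r of 0.359 and a Spearman rho of 0.099, and those of H and NT 0.608 and 0.413.

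Virus status was compared over infested and non-infested Igor plants together, to ask how infected leaves differ from healthy ones. Osmotin (PGSC0003DMG400013227), an antifungal protein, was at an RPKM of 71.4 in CONT_H and 1204 in CONT_PVY, and at 60.8 in CPB_H and 1293 in CPB_PVY (log2 difference 4.22, adjusted p = 0.00674, 2 of 2 pairs). Beta-1 3-glucanase (Sotub02g036210.1.1, 3.34, adjusted p = 0.00819) and Acidic chitinase (Sotub01g032680.1.1, 2.53, adjusted p = 0.0201), both enzymes that attack fungal walls, were higher as well. Calmodulin-binding protein-like Sotub12g018420.1.1 (2.56, adjusted p = 0.0239), WRKY transcription factor 16 (Sotub04g026090.1.1, 2.21, adjusted p = 0.0411) and PGSC0003DMG400025454, of unknown function (2.60, adjusted p = 0.0411), completed the higher host genes. TPR domain protein Sotub07g008250.1.1 was lower (-3.49, adjusted p = 0.0248). In all, 14 genes were higher and 1 lower, of which 8 higher rows were virus sequence. Pathogenesis-related protein 1 (Sotub01g043930.1.1), a marker of salicylic acid responses, was at 203 and 1567 in the controls and 709.8 and 3020 in infested plants, and did not pass (2.52, adjusted p = 0.312). Without the virus rows and with RPKM rescaled, 2 genes passed, Osmotin and the glucanase, both at an adjusted p of 0.0317, and a model of the 4 Igor libraries alone called 562, with 209 higher and 353 lower.

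Of the lists, phenylpropanoid and flavonoid enzymes were lower in PVY (median -0.38, 19 of 91 positive, camera adjusted p = 1.37e-07, and adjusted p = 0.554 with an estimated correlation), with 0 called by limma adjusted over the list alone, 12 at an unadjusted p under 0.05 and 0 by voom. Phenylalanine ammonia-lyase (Sotub05g029380.1.1), the entry enzyme of this pathway, was at 44.5 in CONT_H and 14.3 in CONT_PVY. Cell wall loosening and remodelling genes were lower too (median -0.32, 39 of 123 positive, adjusted p = 4.99e-07, and 0.554 as adjusted p with an estimated correlation), with 1 lower adjusted over the list alone. Over all genes limma called 0, with 25 at an unadjusted p under 0.05, and voom 0. The list median was -0.51 between the controls (percentile 0) and -0.16 between infested plants (percentile 21.5). Expansin-1 (Sotub06g032040.1.1), a wall-loosening protein, was at 48.5 and 5.05 in the controls and 35.9 and 12.9 in infested plants. Disease resistance receptors were higher (median 0.22, 214 of 266 positive, adjusted p = 2.7e-07, and 0.621 as adjusted p with an estimated correlation), with 0 called by limma, 25 at an unadjusted p under 0.05 and 0 by voom. Pathogenesis-related proteins were higher (median 0.19, 33 of 55 positive, adjusted p = 0.00565, and 0.554 as adjusted p with an estimated correlation), with 7 higher adjusted over the list alone and 2 over all genes. Tuber storage proteins were lower (median -0.43, 6 of 20 positive, adjusted p = 0.000725, and 0.554 as adjusted p with an estimated correlation), with 3 lower adjusted over the list alone and, over all genes, 0 called by limma, 6 at an unadjusted p under 0.05 and 0 by voom. Patatin group O (PGSC0003DMG400029247) was at 89.3 in CONT_H and 5.71 in CONT_PVY. Volatile terpene and green leaf aldehyde enzymes (median -0.14, adjusted p = 0.0267, and 0.554 as adjusted p with an estimated correlation) did not pass with median of ratios scaling (0.0886), quantile normalization (0.0941) or a filter at 5 RPKM (0.0773), and had a median of 0.06 between the controls (percentile 24.97) and -0.41 between infested plants (percentile 0.12). WRKY transcription factors (median 0.058, adjusted p = 0.0468, and 0.707 as adjusted p with an estimated correlation) had 2 higher adjusted over the list alone and 1 over all genes, and did not pass with a pseudocount of 5 (0.0569), no filter (0.0808), a filter at 5 RPKM (0.0773) or limma voom (0.0563). This call averages pairs of opposite sign, with a median of 0.52 between the controls (percentile 100) and -0.25 between infested plants (percentile 2.17).

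Compared between single libraries, non-infested PVY leaves had lower photosystem values than non-infested H leaves (median log2 ratio -0.52, percentile 0, 23 of 91 members at least 2-fold lower and 5 higher), and infested PVY leaves had higher ones than infested H leaves (0.61, percentile 100, 28 higher and 5 lower). WRKY transcription factors (0.52), disease resistance receptors (0.37) and heat shock proteins and chaperones (0.28) had higher values in CONT_PVY than in CONT_H, at percentiles of 100, 100 and 99.8. In infested leaves the first and last of these had lower values in PVY (-0.25 and -0.19, percentiles 2.17 and 2.11), and disease resistance receptors higher ones (0.11, percentile 100). Anti-digestive enzymes had lower values in CONT_PVY than in CONT_H (-0.57, percentile 0.12), and between infested leaves their median lay within the central 95% of matched lists (-0.36, percentile 6.37). In infested leaves, proteinase inhibitors (-0.34, percentile 0.01), volatile terpene and green leaf aldehyde enzymes (-0.41, percentile 0.12) and the ethylene pathway (-0.29, percentile 0) had lower values in PVY than in H. Between the controls, proteinase inhibitors (-0.02, percentile 0.25) already lay under the central 95% of matched lists. The volatile list (0.06, percentile 24.97) and the ethylene pathway (0.09, percentile 6.6) lay within it. Glycine rich protein Sotub09g029900.1.1 was at 5.05 in CPB_H and 216 in CPB_PVY. The counts at least 2-fold higher and lower were 897 and 973 in the controls and 559 and 810 in infested plants, and with median of ratios scaling 614 and 1276, and 720 and 609. The median of all genes was 0.17 in the controls and -0.13 in infested plants.

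COI1-silenced plants were compared with NT plants over both infestation states, to ask which genes differ between them. NT plants were not transformed, so transformation and plant line cannot be separated from the silencing. As given above, the silencing itself could not be checked. Patatin-3-Kuras 1 (PGSC0003DMG401017090), a tuber storage protein, was at an RPKM of 69.3 in CONT_NT and had 2 units in CONT_coi1, a ratio of 0.00202 (0.000241 to 0.00722), with 0 units in CPB_coi1 against an RPKM of 28.9 in CPB_NT (log2 difference -5.40, adjusted p = 0.0458). Acid phosphatase Sotub03g035860.1.1 was at 109 and 7.35 in the controls and 282 and 5.72 in infested plants (-4.56, adjusted p = 0.0432, 2 of 2 pairs). Spermidine synthase (Sotub06g017400.1.1), of polyamine synthesis, and BURP domain-containing protein Sotub05g013240.1.1 were lower by log2 differences of -3.82 and -3.75, each at an adjusted p of 0.0494. Beta-1 3-glucanase Sotub01g009310.1.1 (2.99, adjusted p = 0.0458), 1-aminocyclopropane-1-carboxylate oxidase 1 (Sotub06g023790.1.1, 2.79, adjusted p = 0.0494) and WRKY transcription factor 16 (2.78, adjusted p = 0.0432) were higher in coi1. In all, 8 genes were higher and 4 lower.

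The count of 12 was 0 with median of ratios scaling, quantile normalization, no filter or the 4 Desiree libraries alone, by limma with 3061, 3098, 3744 and 2767 genes at an unadjusted p under 0.05. It was 65 by voom, with 19 higher and 46 lower, and 40 with a pseudocount of 0.1, with 19 higher and 21 lower. Median of ratios scaling also moved the median of all genes in this contrast from 0.21 to 0.03.

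Of the lists that passed with the preset correlation, 9 had lower values in coi1, among them both jasmonate lists and proteinase inhibitors, and WRKY transcription factors and ribosomal proteins had higher values. Proteinase inhibitors had a median of -0.42 and a mean of -1.82 (26 of 66 positive, camera adjusted p = 3.27e-06, and adjusted p = 0.429 with an estimated correlation), with 20 lower and 2 higher adjusted over the list alone. Jasmonate biosynthesis had a median of -0.70 (6 of 22 positive, adjusted p = 7.76e-06, and 0.303 as adjusted p with an estimated correlation), with 8 lower and 2 higher adjusted over the list alone, and jasmonate signalling -0.41 (3 of 15 positive, adjusted p = 7.49e-05, and 0.342 as adjusted p with an estimated correlation), with 5 lower and 1 higher. Volatile terpene and green leaf aldehyde enzymes had a median of -1.11 (9 of 29 positive, adjusted p = 5.3e-07, and 0.303 as adjusted p with an estimated correlation), with 9 lower and 1 higher adjusted over the list alone. Cell wall loosening and remodelling had a median of -0.63 (39 of 123 positive, adjusted p = 1.27e-13, and 0.303 as adjusted p with an estimated correlation), with 38 lower and 6 higher adjusted over the list alone. Phenylpropanoid and flavonoid enzymes had a median of -0.46 (28 of 91 positive, adjusted p = 1.85e-10, and 0.303 as adjusted p with an estimated correlation), with 21 lower and 3 higher adjusted over the list alone. Sterol and isoprenoid precursor enzymes had a median of -0.28 (17 of 43 positive, adjusted p = 0.00014, and 0.342 as adjusted p with an estimated correlation), with 6 lower and 1 higher adjusted over the list alone. Over all genes limma called 0 in each of these 7 lists, with 31, 11, 8, 14, 58, 43 and 16 members at an unadjusted p under 0.05, and voom called 6, 3, 1, 3, 2, 2 and 0. Light harvesting and photosystem genes had a median of -0.79 (15 of 91 positive, adjusted p = 2.51e-12, and 0.454 as adjusted p with an estimated correlation), with 1 lower adjusted over the list alone and, over all genes, 0 called by limma, 18 at an unadjusted p under 0.05 and 0 by voom. Tuber storage proteins had a median of -0.19 (9 of 20 positive, adjusted p = 0.00563, and 0.303 as adjusted p with an estimated correlation), which was 0.013 with a pseudocount of 5, with 4 lower and 1 higher adjusted over the list alone and 1 lower over all genes. Their median was -0.09 between the controls (percentile 6.64) and -0.53 between infested plants (percentile 0.02). WRKY transcription factors had a median of 0.62 (46 of 54 positive, adjusted p = 2.45e-05, and 0.629 as adjusted p with an estimated correlation), with 8 higher adjusted over the list alone and 1 over all genes. Cytosolic ribosomal proteins had a median of 0.41 (225 of 264 positive, adjusted p = 0.00058, and 0.802 as adjusted p with an estimated correlation), with 0 called by limma, 29 at an unadjusted p under 0.05 and 0 by voom. Their median was 0.67 between infested plants (percentile 100) but 0.16 between the controls (percentile 21.5, and 1.51 among lists matched also on length).

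The other 16 lists did not pass. Anti-digestive enzymes (median -0.27, mean -1.65, 9 members, adjusted p = 0.0552) passed with a pseudocount of 0.1 (0.0495) and by voom (0.0179), and disease resistance receptors (median 0.24, 266 members, adjusted p = 0.234) with quantile normalization (0.0388). Pathogenesis-related proteins had a median of 0.54 (55 members, adjusted p = 0.603), with 10 higher and 6 lower adjusted over the list alone and, over all genes, 0 called by limma, 28 at an unadjusted p under 0.05 and 0 by voom. The medians of cytochrome P450 enzymes (0.010), Rubisco and Calvin cycle (0.091) and starch and sucrose metabolism (0.11) were -0.132, -0.107 and -0.088 with median of ratios scaling and -0.063, -0.052 and -0.071 with quantile normalization, and that of cell division and histones (0.15) was -0.026 with median of ratios scaling.

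Between single libraries, the widest gaps of single genes lay in infested plants. The lowest log2 ratio of a described gene was -12.60 there, for Aspartic protease inhibitor 1. In the controls it was -7.42, for FAD binding domain-containing protein (Sotub02g015720.1.1). Some other gaps were smaller. Lipoxygenase Sotub01g007050.1.1, which starts oxylipin synthesis, was at an RPKM of 3867 in CPB_NT and 205 in CPB_coi1, and Cysteine-rich extensin-like protein-2 (Sotub01g006850.1.1) at 6459 and 226. Another Lipoxygenase (Sotub01g037000.1.1) was at 3.45 and 319, and Cytochrome P450 Sotub09g011440.1.1 at 13.7 and 865. Volatile terpene and green leaf aldehyde enzymes had a median log2 ratio of -1.80 in infested plants and -0.41 in controls, proteinase inhibitors -0.95 and -0.52, jasmonate biosynthesis -0.89 and -0.51, and jasmonate signalling -0.84 and -0.30, at percentiles of 0 to 0.68. The order was the reverse for phenylpropanoid and flavonoid enzymes (-0.27 in infested plants and -0.67 in controls), cell wall loosening and remodelling (-0.54 and -0.65) and sterol and isoprenoid precursor enzymes (-0.09 and -0.28). In the controls, Sterol reductase (Sotub06g030060.1.1) was at 452 in CONT_NT and 12.2 in CONT_coi1, and Sterol 4-alpha-methyl-oxidase 2 (Sotub01g030430.1.1), likewise of sterol synthesis, at 487 and 9.56. Pathogenesis-related protein 1 Sotub01g043890.1.1 was at 1.9 and 41.5, and Transcription factor bHLH96 (Sotub11g009360.1.1) at 24.9 and 309. The counts at least 2-fold higher and lower in coi1 were 2010 and 1474 in infested plants and 1250 and 1283 in controls, and with median of ratios scaling 1305 and 2003, and 935 and 1465. The median of all genes was 0.24 in infested plants and 0.15 in controls.

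The response of coi1 plants to feeding was set against that of NT plants. Anti-feeding genes made up the lowest differences. The difference in log2 ratio was -10.23 for Proteinase inhibitor II, -9.45 for Cysteine proteinase inhibitor, -9.25 for Aspartic protease inhibitor 1, -8.55 for Polyphenol oxidase Sotub08g017890.1.1 and -8.29 for Alpha-amylase inhibitor (Sotub03g015960.1.1), which acts on a digestive enzyme of insects. Jasmonate signalling had a median difference of -0.86, proteinase inhibitors of -0.83 and volatile terpene and green leaf aldehyde enzymes of -0.77, each at percentile 0. Of these lists 6, 31 and 14 members were at least 2-fold lower, and 0, 8 and 8 higher. Jasmonate biosynthesis differed by -0.27 (percentile 1.46), a value that was 0.153 with a filter at 5 RPKM. Anti-digestive enzymes differed by -0.253 (percentile 7.06), within the range of -0.409 to 0.65 of matched lists. Of their 9 members, 3 were at least 2-fold lower and 2 higher. Light harvesting and photosystem genes differed by -0.61 (percentile 0), and glutathione transferases and peroxidases by 0.36 and cytosolic ribosomal proteins by 0.47, both at percentile 100. G-type lectin S-receptor-like kinase Sotub02g019410.1.1 (5.54) and Pectinesterase Sotub12g023810.1.1 (5.30), an enzyme of cell wall pectin, had among the highest differences, and the former went from 8.78 to 1125 in the coi1 pair and from 12.3 to 32.0 in the NT pair. Across genes, the NT and coi1 responses had a Pearson r of 0.431 and a Spearman rho of 0.349.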

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

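Of the tests in this part, those of virus profile, virus share, scaling, gene length and hour of collection were chosen only after the result was seen, and that of carried-over reads was chosen before.

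Virus sequence appeared in libraries of plants labelled healthy or non-transformed, with 472 units in CPB_H, 629 in CONT_H and 352 in CONT_NT, above the 0 to 1 units of the other Desiree libraries. Potato sequence that resembles the virus is argued against, because the 8 virus rows kept the profile of the PVY libraries, with correlations of log2 RPKM of 0.996 in CPB_H, 0.992 in CONT_H and 0.979 in CONT_NT. Reads or RNA carried over from a PVY library into CONT_NT cannot be told apart from other sources. Transcripts of CONT_PVY with 0 units in the other Desiree libraries had 27 units in CONT_NT (17.8 to 39.3) over 56 transcripts, where carry-over predicts 2.3, and those of CPB_PVY also 27 over 52 transcripts, where it predicts 9.9, but the same count in the other Desiree libraries, where 0 was predicted, ran from 4 to 309. Traces of infection in the H and NT plants stay open as an untested biological explanation.

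Light harvesting and photosystem genes (91 members) had a median log2 ratio of -0.817 in the H pair and 0.45 in the PVY pair, and this difference was not tested against replicates. The share of units taken by the virus is argued against, since it moved the log2 values of all host genes of the PVY pair by only 0.024. Library scaling is argued against as the whole cause, since with median of ratios scaling the medians were -0.966 in H and 0.589 in PVY, and so is gene length, since the median difference of 1.134 lay outside the range of -0.419 to -0.122 of lists matched on expression and length. A different hour of collection cannot be told apart, since the median absolute difference of the clock list (48 members) of 0.424 stood at percentile 16.96, within the central 95% of matched lists, and in the PVY pair alone its median was -0.303 (percentile 1.35). The virus status itself, the state of the single pools compared and the container remain open and untested.

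Other lists had medians of opposite sign in the backgrounds compared, some of them close to 0, and these differences were not tested. Cell wall loosening and remodelling genes (123 members) had a median of -0.13 in H and 0.495 in PVY, but means of 0.066 and 0.514. Cytochrome P450 enzymes (198 members) had a median of 0.006 in NT and -0.169 in coi1, but means of 0.116 and 0.055, and disease resistance receptors (266 members) 0.05 in NT and -0.148 in coi1.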

How the results depend on the processing

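Of the tests in this part, those by limma voom and those without the virus rows were chosen only after the result was seen. The number of genes called is the least stable result: the 201 of the infestation contrast became 86 with a pseudocount of 5, 2 with no filter, 82 with median of ratios scaling, 106 with quantile normalization, 51 with no background block and 509 with voom, and ran from 2 (without the H pair) to 465 (without the coi1 pair) over the pairs left out. The 15 of the virus contrast, of which 7 were not virus rows, became 562 in the model of the 4 Igor libraries, which has a single residual degree of freedom. The 7 became 2 in the run without the virus rows. The 12 of the coi1 contrast became 40 and 2 with pseudocounts of 0.1 and 5, 0 with no filter, median of ratios scaling, quantile normalization or the 4 Desiree libraries (3744, 3061, 3098 and 2767 genes at an unadjusted p under 0.05 by limma), and 65 with voom. Genes at least 2-fold different were more with a pseudocount of 0.1, with 2420 in the PVY pair, 2845 between CONT_PVY and CONT_H and 2121 between CPB_PVY and CPB_H. With a pseudocount of 5 they numbered 1243 in H, 768 in PVY, 1166 in NT, 2135 in coi1, 918 between CONT_PVY and CONT_H, 704 between CPB_PVY and CPB_H, 1344 between CONT_coi1 and CONT_NT and 2093 between CPB_coi1 and CPB_NT. The correlation of the PVY and H responses was 0.342, 0.380 and 0.394 with a pseudocount of 0.1, a pseudocount of 5 and a filter at 5 RPKM, and that of coi1 and NT 0.416 and 0.456 with the last 2 settings. Of the list medians with a call, or a percentile outside the central 95%, in either run, those that changed sign were those of cytochrome P450 enzymes in the infestation contrast (-0.093 to 0.028 over the pairs left out, 0.026 without the coi1 pair) and tuber storage proteins in the coi1 contrast (0.013, pseudocount of 5). With a filter at 5 RPKM the sign changed for the salicylic acid pathway in H (0.226), pollen and flower proteins in PVY (0.151) and between CONT_PVY and CONT_H (0.007), and, in the response of coi1 minus NT, for jasmonate biosynthesis (0.153), the ethylene pathway (-0.076) and tuber storage proteins (-0.927). With median of ratios scaling it changed for cell division and histones in H (-0.068), the ethylene pathway in PVY (0.077), auxin response (-0.119) and cytochrome P450 enzymes (-0.033) between CONT_PVY and CONT_H, glutathione transferases and peroxidases between CPB_PVY and CPB_H (0.066) and heat shock proteins and chaperones between CONT_coi1 and CONT_NT (-0.072). With quantile normalization it changed for sterol and isoprenoid precursor enzymes in the response of PVY minus H (0.186). The cause was not tested for any of these. Of the results for named genes of the model, 287 kept direction and call and 179 kept direction only. Of the list medians of the model 845 kept both, 23 gained and 18 lost a call, 2 changed sign with a call and 30 without any, and of those of single comparisons 963, 18, 32, 13 and 54 did so.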

Other observations

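Of the tests in this part, all were chosen only after the result was seen, as was the contrast of cultivars.

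RPKM values of the healthy Igor and the non-transformed Desiree plants differed in 444 genes, with 202 higher in Igor and 242 higher in Desiree (limma with Benjamini-Hochberg adjustment, 18842 genes tested), and no alternative was run for this contrast. Proteinase inhibitor II Sotub03g024780.1.1 was at an RPKM of 974.9 and 537 in CONT_NT and CPB_NT and at 3.12 and 3.72 in CONT_H and CPB_H (log2 difference -7.36, adjusted p = 0.00208, 2 of 2 pairs), and so did not follow feeding as Proteinase inhibitor II Sotub03g012360.1.1 did. Acid phosphatase Sotub03g035860.1.1 was lower in Igor by a log2 difference of -6.85 (adjusted p = 0.000377). The ribosomal protein gene Sotub04g013740.1.1 (60S ribosomal protein L3) had 0 units in the 4 Igor libraries and an RPKM of 147 to 213 in the 4 Desiree libraries, and Sesquiterpene synthase Sotub07g009620.1.1 had 0 units in Igor and an RPKM of 277 in CPB_NT. COP9 signalosome complex subunit 6a (Sotub10g005960.1.1), part of a regulator of protein degradation, was at 57.9 to 88.8 in the Igor libraries and had 0 to 2 units in the Desiree libraries. Igor also had higher values of Osmotin (PGSC0003DMG400013227, 3.77, adjusted p = 0.00189) and WRKY transcription factor 16 (Sotub04g026090.1.1, 2.38, adjusted p = 0.00355), and the WRKY list had a median of 0.25 (camera adjusted p = 0.00303, and adjusted p = 0.999 with an estimated correlation). Pathogenesis-related proteins had a median of 0.31 (adjusted p = 0.0118, and 0.999 as adjusted p with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone and 5 and 1 over all genes. Cultivar and the growth of the 2 sets of plants cannot be separated here. Whether a row with 0 units in a cultivar lacked the transcript or only reads that matched the row was not tested.

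The values of a single heat shock gene, which were not tested, varied between libraries. Class I heat shock protein Sotub06g032310.1.1, which protects other proteins from clumping, was at 22.6 in CONT_H, 187 in CONT_PVY, 82.6 in CONT_NT and 96.2 in CONT_coi1, and at 61.9, 23.6, 21.1 and 42.3 in the infested libraries of the same backgrounds.

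Some anti-feeding genes stood near 0 in CPB_coi1, such as Aspartic protease inhibitor 1 (1.27) and Threonine dehydratase (0.61), while 10 of 66 proteinase inhibitors were at least 2-fold higher there than in CONT_coi1. Of the 342 genes at least 2-fold higher in the infested libraries of H, PVY and NT, 166 were so in CPB_coi1 too (48.5%, against 9.1% of matched random genes, 6.1 to 12.6). This argues against a CPB_coi1 library from plants kept like the controls. It cannot argue against plants that stood in a container without being fed on, because container and infestation are confounded. Swapped labels of the coi1 libraries are argued against, because only 23 of those 342 genes were at least 2-fold lower in CPB_coi1. Lighter feeding on these plants cannot be told apart, because the amount of feeding is not given in the sources used here. Glutathione transferases and peroxidases had a response higher in coi1 than in NT by a median of 0.363 (percentile 100, and above the central 95% of matched lists in every setting). Whether that list follows the amount of feeding, or itself changes with the silencing, was not tested. Loss of the jasmonate receptor stays open as a biological explanation, untested because the silencing could not be read from the COI1 row.

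The 8 libraries can be split into 2 groups of 4 in 35 ways, 32 of which the background block can estimate. The real split called 201 genes and the highest of the others called 0. Only 8 splits part all 4 pairs and 1 of them, the real split, called as many genes, so the splits are too few for a share under 0.05.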
